A study of Enchytraeus albidus with 15 samples.

How the data were processed

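Gene expression was measured in Enchytraeus albidus, the white potworm, a small oligochaete of soil used in ecotoxicity tests. Per the labels' protocols, 10 adult worms with a developed clitellum were kept in each vessel of 25 g moist soil for 2 days at 20 °C with 16 h of light and 8 h of dark. The soil was clean OECD soil, a standard artificial test soil, or the same soil spiked with silver nitrate (AgNO3, a soluble silver salt) or silver nanoparticles (Ag-NP) at 100 or 200 mg/kg. Each of the 5 groups had 3 biological replicates, the worms of 1 replicate were extracted together, and each replicate was hybridised to 1 array, which gave 15 arrays. Whole bodies were extracted with Trizol, and Cy3-labelled cRNA was made from 0.5 µg of total RNA for hybridisation in 1 colour.

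Per the file headers, the authors' deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 10.5.1.1, which the submitters' processing notes name too. The processed intensity in the deposited files was background-subtracted within the array and had low values replaced, per the file headers, and was not scaled between arrays. The deposited files also mark, per spot, whether the signal was well above background, saturated or an outlier within its replicates. The authors' deposited table of the whole series holds 1 log2 value per spot and array, without centring on each probe. Each of its columns had the same median of 5.53 and the same 75th percentile of 7.86. Its values correlated with the log2 processed intensity of the same array at r = 0.967 to 0.993 across spots, with slopes of 0.890 to 1.04, so the table was read as log2 with the direction of the scanner values. How the authors normalized that table is not given in the sources used here. Between 20.6 and 44.3% of the spots had no value in a column of the table, and none of these spots was well above background.

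Each array held 15744 spots, of which 536 were control spots and 15208 belonged to 1035 probes with 14 or 15 spots each. Control spots and spots marked as outliers were left out, and saturated spots were kept. The log2 of the processed intensity was averaged over the spots of a probe, and the array's 75th percentile over its non-control spots was subtracted, so levels are given as log2 relative to that percentile. A probe counted as well above background on an array when a share of at least 0.5 of its remaining spots did. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 446 probes and left out 589. The probe names in the files are clone and contig names with no gene name or description, and no table pairing them with genes was used. For this reason the 24 gene lists and the annotation terms planned before the data were examined could not be tested, and results are given per probe.

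Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in 1 fit of all 15 arrays with the group as the only term, which left 10 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 10 comparisons: each silver group against control, Ag-NP against AgNO3 at each concentration, 200 against 100 mg/kg of each form, the interaction of form and concentration, and the mean of the 4 silver groups against control. A probe is said to have risen, fallen or changed when its adjusted p was below 0.05, and errors of fold changes are standard errors of that fit. The design, this rule, the named probes' rule and most alternatives were set before the data were examined. The rule named, for probes without a description, up to 2 rises and 2 falls per comparison: those with the largest change among probes past the threshold, with all 3 arrays of one group beyond all 3 of the other and well above background on all 3 arrays of the brighter group. Where no probe passed, those with the smallest p were named and are said not to have passed. A probe not well above background on any array of 1 group has only a bound there. Its fold is given as at least the difference between the bright group's mean and the mean of the higher, per array, of the dim probe's own signal and the lowest signal among probes well above background. This bound concerns the means and leaves out their sampling error.

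The 1035 probe names fall into 4 kinds by their first letters: 171 begin with Contig, 345 with Ealb_Met, 198 with Ealb_Pest, and 321 are other clone names. The files do not explain these prefixes. The kinds were compared with limma's camera (preset inter-probe correlation of 0.01, and again with an estimated correlation) and with two-sided Fisher's exact tests, a grouping chosen after the names were seen. Correlations of fold changes across probes were set beside 100 simulations of unchanged groups that shared the control arrays, made by shuffling the deviations from the group means among the arrays. The shuffling took no account of slide, so the simulated values may miss what the uneven placement of groups on slides adds. Lists of probes chosen with AgNO3 were set beside lists of the same numbers of rises and falls with the smallest p in such simulations, a comparison added after the result was seen. The 3 control arrays were too few to split between comparisons.

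The fit was tested on simulated data before use. In 20 simulated data sets of 446 probes and 15 arrays, with 60 probes changed between AgNO3 at 200 mg/kg and control, it recovered 16.5% of 2-fold, 82.0% of 4-fold and 95.0% of 8-fold changes, and 3.73% of its calls were false. With slide as a block, simulated for Ag-NP at 100 mg/kg against control on 446 probes, it recovered 64.3% of 4-fold and 91.5% of 8-fold changes, with 44 false calls among 979. The camera step, on 446 probes, found a simulated shift of 0.50 log2 units in the Ealb_Pest probes in 20 of 20 runs and no shifted kind in the unchanged group. In all these simulations the noise was drawn independently for each probe, whereas many real probes moved together. The rates of recovery and of false calls may therefore not hold for the real arrays.

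The files place the arrays on 3 slides scanned on 2 days. Slide 1 held 5 arrays and slide 2 held 4, both scanned on the first day, and slide 3 held the other 6, scanned on the second day, so slide 3 and the second day cannot be separated. Control and AgNO3 at 200 mg/kg had 1 array on each slide, AgNO3 at 100 mg/kg had 1 on slide 1 and 2 on slide 2, Ag-NP at 200 mg/kg had 2 on slide 1 and 1 on slide 3, and all 3 arrays of Ag-NP at 100 mg/kg were on slide 3. Every comparison was therefore also fitted with slide as a block and within each slide that held both groups, where 1 or 2 residual degrees of freedom remained and at least 1 of the groups compared was a single array, assumed to vary like the others.

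Other alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, scaling to the array median or to the 75th percentile of the probes above background on all arrays, the authors' table, no filter, only probes above background on all arrays, eBayes with trend and robust, a fit of only the arrays compared, the replicate number as a block, a 2-fold minimum, and leaving out each array in turn. The normexp alternative used the median spot signal, because the mean signal it was planned on is not among the columns of the scanner files used here. Chosen after the data were seen were the array's brightness (its log2 75th percentile) as a covariate, scaling to the spike-in spots, leaving out 3 arrays whose negative-control spots varied most (spread above 7), slide and brightness together, and the fits within slides. No array's values were identical to another's. Precision is limited by the number of arrays.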

Results

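Transcript levels in whole adult Enchytraeus albidus were measured on 15 one-colour arrays after 2 days in clean soil or in soil with silver nitrate (AgNO3) or silver nanoparticles (Ag-NP) at 100 or 200 mg/kg, with 3 replicates per group. The comparisons address how the worms' transcript levels respond to each silver form and concentration, and whether the forms act alike. Of the 1035 probes on the array, 446 were tested and 227 were well above background on all 15 arrays. The number of probes well above background ranged from 251 (24.3%) to 589 (56.9%) per array, with a median of 455. The 75th percentile of the processed signal, here called the brightness of an array, ranged from 16.9 to 54.3 with a median of 21.9, and between 11 and 13 probes per array were saturated. The spots of a probe had a median SD of 0.10 to 0.16 log2 units within an array, below the median SD of a probe between replicates, which was 0.44 in control, 0.49 and 0.46 with AgNO3 at 100 and 200 mg/kg, and 0.59 and 0.39 with Ag-NP at 100 and 200 mg/kg.

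The arrays differed in brightness within groups, and levels after scaling still moved with it. The first principal component of the tested probes held 46.4% of the variance and correlated with log2 brightness over the 15 arrays at Pearson's r = 0.73 (permutation p = 0.0017, 0.0034 after Benjamini-Hochberg adjustment over 2 tests) and Spearman's rho = 0.57 (permutation p = 0.028, 0.028 after adjustment). Without the 2 arrays farthest from the median brightness r was 0.61. It was 0.69 over the 9 arrays of the first scan day and 0.89 over the 6 arrays of the second. Among deviations from the group means r was 0.88. Each comparison was therefore also fitted with brightness as a covariate.

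AgNO3 at 200 mg/kg changed 48 of the 446 probes against clean soil, and 35 of them rose while 13 fell (limma). The probe Ealb_Met_P6_D6_SP6_2090551 rose 6.79-fold, from -1.27 ± 0.35 in control to 1.49 ± 0.38 with AgNO3 (log2 level, mean ± SD, n = 3 each), a log2 fold change of 2.76 ± 0.55 (SE, adjusted p = 0.0119). It was above background on 2 of 3 control arrays. P5_B9_T7_1329852 rose 6.51-fold, a log2 fold change of 2.70 ± 0.72 (adjusted p = 0.03), from a level of -2.24 ± 0.35 at which 2 of 3 control arrays were above background. Contig11 fell 14.6-fold, from 1.49 ± 0.37 to -2.38 ± 1.42, a log2 fold change of -3.87 ± 0.68 (adjusted p = 0.0107), and only 1 of 3 AgNO3 arrays measured it above background. P5_D7_T7_1329838 fell 5.32-fold, from 3.68 ± 0.91 to 1.27 ± 0.34 (adjusted p = 0.0195). The median log2 fold change was 1.66 among the probes that rose and -1.85 among those that fell, beside a median standard error of 0.45 over all tested probes.

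All 48 probes had the 3 AgNO3 arrays beyond the 3 control arrays, as had 32.5% of the tested probes, where chance gives 10%, and 127 probes had an unadjusted p below 0.05, where 22.3 would arise by chance. Probes that move together spread more widely around these chance values, by an amount that was not estimated. The first principal component alone placed the AgNO3 arrays (-0.48 to -0.22) below the control arrays (-0.15 to 0.29). The excess therefore does not show how many probes changed. When slide was a block 13 probes rose and 11 fell, all 24 of them among the 48, and P5_B9_T7_1329852 had an adjusted p of 0.0535 with that block and 0.0549 with brightness as a covariate (0.00198 to 0.996 over its 33 alternatives). Within slides 1, 2 and 3 alone, 51, 1 and 0 probes passed in limma, 16 of the 51 being among the 48. In each of these fits 1 AgNO3 array stood against 1 control array, and the spread came only from the 2 Ag-NP 200 mg/kg arrays on slide 1, the 2 AgNO3 100 mg/kg arrays on slide 2 and the 3 Ag-NP 100 mg/kg arrays on slide 3. The count was 10 without control replicate 1, 16 without control replicate 2, 30 without AgNO3 200 mg/kg replicate 1 and 8 without its replicate 3. The share of rises depended on the arrays and the scaling. There were 20 rises to 35 falls without the 3 arrays of high negative-control spread (28 of these 55 among the 48), 12 to 18 without AgNO3 200 mg/kg replicate 1, 4 to 4 without its replicate 3 and 24 to 19 without control replicate 3. The share was 35 rises to 13 falls with the 75th percentile, 25 to 18 with normexp and quantile normalization, 19 to 16 with the percentile of probes above background on all arrays, 7 to 11 with spike-in scaling and 2 to 6 in the authors' values. The median log2 fold change of all tested probes was -0.21 with the 75th percentile, -0.29 with the array median, -0.87 with spike-in scaling, -0.38 in the authors' values and -0.06 with normexp, and it was not subtracted from the fold changes. Beyond it the 35 rises had a median of 1.87 and the 13 falls of -1.64 with the 75th percentile.

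**Figure D1:**
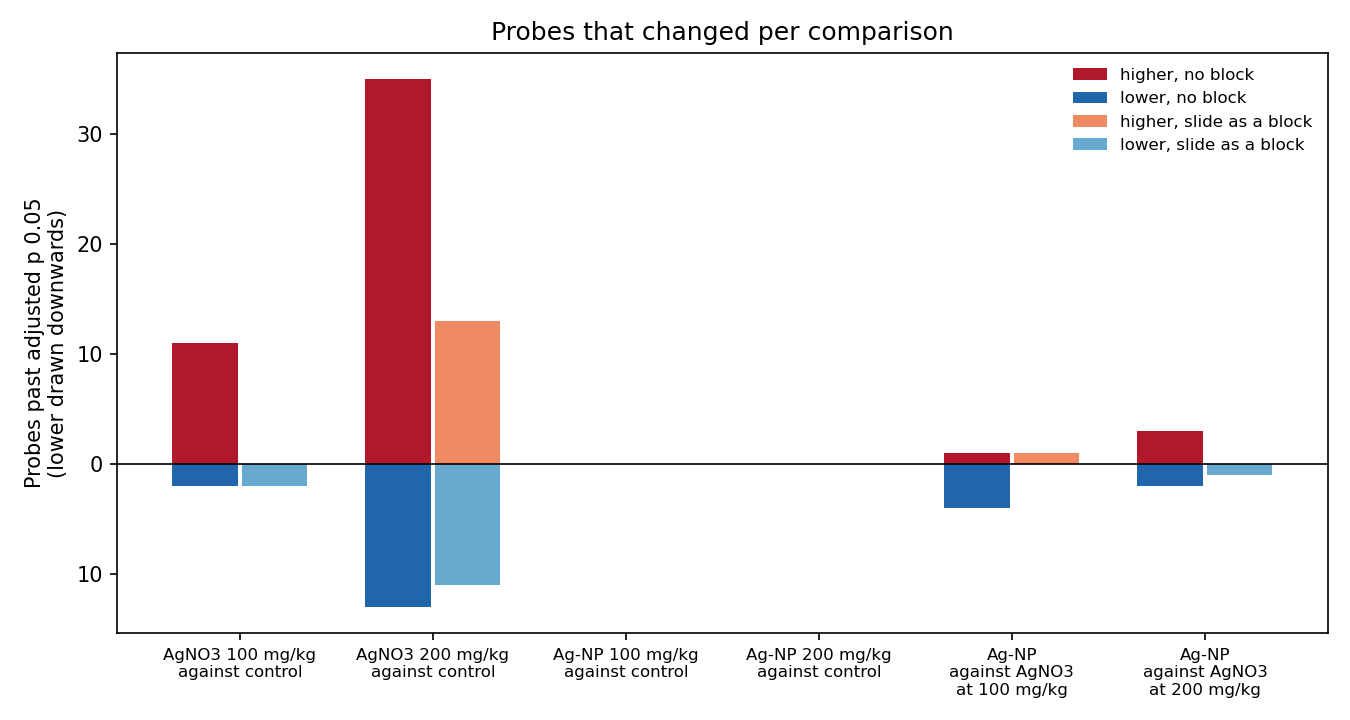
Number of probes past an adjusted p of 0.05 (limma) in each of 6 comparisons, with probes that were higher drawn upwards from 0 and probes that were lower drawn downwards, without a block (dark bars) and with slide as a block (light bars). AgNO3 at 200 mg/kg gave 35 rises and 13 falls without a block and 13 and 11 with it, and neither Ag-NP group gave any.

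AgNO3 at 100 mg/kg changed 13 probes against clean soil, of which 11 rose and 2 fell (limma). Ealb_Met_P6_D6_SP6_2090551, above background on 2 of 3 control arrays, rose 6.09-fold, a log2 fold change of 2.61 ± 0.55 (SE, adjusted p = 0.0363), to a level of 1.34 ± 0.77 (SD, n = 3). Ealb_Met_P3_G12_SP6_2090418 rose 4.55-fold, from 3.62 ± 0.46 in control to 5.81 ± 0.79 (adjusted p = 0.0363). P5_D7_T7_1329838 fell 8.45-fold, from 3.68 ± 0.91 to 0.60 ± 0.55, a log2 fold change of -3.08 ± 0.57 (adjusted p = 0.0333). P2_B1_T7_1328894 fell 4.38-fold, from 4.44 ± 0.73 to 2.31 ± 0.35 (adjusted p = 0.0363). All 13 probes had the 3 AgNO3 arrays beyond the 3 control arrays, against 15.9% of the tested probes, and 53 probes had an unadjusted p below 0.05.

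Only 2 probes changed with AgNO3 at 100 mg/kg when slide was a block, P5_D7_T7_1329838 (adjusted p = 0.0035, 0.00324 to 0.998 over its 33 alternatives) and P2_B1_T7_1328894 (0.0195, 0.0137 to 0.998), both among the falls. Both named rises then had an adjusted p of 0.0781, within 0.00975 to 0.998 over the alternatives for Ealb_Met_P6_D6_SP6_2090551 and 0.0124 to 0.998 for Ealb_Met_P3_G12_SP6_2090418. Within slide 1 alone 2 probes passed, and within slide 2 none of the 446 did. The count was 21 with brightness as a covariate, all 13 probes among them. No probe passed without control replicate 1, control replicate 2, AgNO3 100 mg/kg replicate 1 or 3, or Ag-NP 200 mg/kg replicate 2, while 1 passed without control replicate 3, 4 without Ag-NP 200 mg/kg replicate 3 and 25 without Ag-NP 100 mg/kg replicate 1. The 11 rises and 2 falls became 6 and 5 with normexp and quantile normalization, 0 and 2 with the percentile of probes above background on all arrays, and 3 and 0 with spike-in scaling.

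The AgNO3 concentrations shared 12 of the 13 probes that changed at 100 mg/kg, 10 of them rises and 2 falls, where lists of these sizes from unchanged groups sharing the control arrays had 4.36 ± 3.37 rises and 0.59 ± 0.767 falls in common (mean ± SD of 100 simulations, 11 of which reached 10 rises and 17 of which reached 2 falls). The 35 probes that rose at 200 mg/kg had a median log2 fold change of 1.36 at 100 mg/kg and were above 0 in 35 of 35, and 22 of them passed adjusted over the list alone, against 10 over all probes. The 13 that fell had a median of -1.24 at 100 mg/kg, and 12 of them passed adjusted over the list alone, against 2 over all probes. Both lists were chosen on the same control arrays. Lists chosen alike from unchanged groups had a median of 0.44 ± 0.50 for the rises and -0.51 ± 0.53 for the falls, all 35 rises above 0 in 26 of 100 simulations, and as many passes over the list alone in 2 of 100 for the rises and 5 of 100 for the falls. Across the 446 probes the fold changes at the 2 concentrations correlated at Pearson's r = 0.48 and Spearman's rho = 0.36, and unchanged groups sharing the control arrays gave 0.43 ± 0.33 (SD of 100 simulations). Their covariance was 0.319, beside a simulated 0.15 ± 0.184 (SD). Part of the overlap may come from the shared control arrays, which were too few to split, and probes are not independent replicates. The number of shared probes was 2 with slide as a block, 2 within slide 1 and 0 within slide 2. It was 0 without control replicate 1, control replicate 2, AgNO3 100 mg/kg replicate 1 or 3, or Ag-NP 200 mg/kg replicate 2, and 1, 4, 5 and 23 without control replicate 3, Ag-NP 200 mg/kg replicate 3, AgNO3 200 mg/kg replicate 3 and Ag-NP 100 mg/kg replicate 1.

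Between 200 and 100 mg/kg of AgNO3 no probe passed in limma, and 88 had an unadjusted p below 0.05 beside 22.3 by chance. The named probes with the smallest p had log2 differences of 1.43 ± 0.43 (SE) for Ealb_Met_P3_H11_T7_2175244 and 1.39 ± 0.43 for Ealb_Met_P8_F8_SP6_2091134. At the other end Ealb_Pest_P2_H2_SP6_2091268 had -1.97 ± 0.55, with only 1 of the 3 arrays at 200 mg/kg above background, so its size is uncertain. Ealb_Met_P9_B10_SP6_2090756, below background on all 3 arrays at 200 mg/kg, had a mean at least 3.03-fold lower there, which did not pass. All 4 had an adjusted p of 0.17. No probe passed in limma with slide as a block or within slide 2 either, but 29 did within slide 1 alone and 26 did without AgNO3 100 mg/kg replicate 3.

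Ag-NP at 200 mg/kg changed no probe against clean soil in limma, with 44 probes at an unadjusted p below 0.05 where chance gives 22.3, and a smallest adjusted p of 0.382. The named probes, none of which passed, were P2_C1_T7_1328895 with a log2 difference of 2.77 ± 0.73 (SE) and Ealb_Met_P3_C7_SP6_2090377, at least 4.15-fold above control arrays that did not measure it above background. On the lower side Ealb_Met_P8_C1_SP6_2090691 had -1.31 ± 0.39 and Ealb_Met_P6_D3_SP6_2090528 had -1.07 ± 0.35. The former was above background on 2 of 3 Ag-NP arrays and the latter on 2 of 3 control arrays. Each of these 4 had an adjusted p of 0.382. The 35 probes that rose with AgNO3 at 200 mg/kg had a median log2 difference of 0.82 with Ag-NP at 200 mg/kg and were above 0 in 35 of 35, and the 13 that fell had a median of -0.59 and were below 0 in 11 of 13. None of these 48 passed adjusted over the list alone. Both comparisons share the control arrays, and lists chosen alike from unchanged groups had all 35 rises above 0 in 28 of 100 simulations and at least 11 of 13 falls below 0 in 68 of 100. Over all 446 probes 54.7% had the same sign in both comparisons, beside a simulated 67.7%.

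For Ag-NP at 200 mg/kg no probe passed in limma with slide as a block or within slide 3 alone, while within slide 1 alone 6 were higher and 9 lower. Without Ag-NP 200 mg/kg replicate 1, 9 probes fell. The median difference of all tested probes was 0.12 with the 75th percentile and -0.29 with spike-in scaling.

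Ag-NP at 100 mg/kg changed no probe against clean soil in limma, and 10 probes had an unadjusted p below 0.05, fewer than the 22.3 that chance gives. The probe with the smallest p was Ealb_Met_P10_G3_SP6_2090800 (adjusted p = 0.4). It was not well above background on any Ag-NP 100 mg/kg array, and its bound left no size to give. Ealb_Met_P10_F3_SP6_2090799, also below background on these arrays, had a mean at least 1.02-fold lower, which did not pass (adjusted p = 0.705). P5_C1_SP6_1372024 had 1.29 ± 0.37 (log2 difference ± SE, adjusted p = 0.705) and Contig50 had 1.32 ± 0.54 (adjusted p = 0.996). Each was above background on only 1 control array and 2 Ag-NP 100 mg/kg arrays, so these sizes are uncertain. The 35 probes that rose with AgNO3 at 200 mg/kg had a median of 0.26 here and were above 0 in 31 of 35, and the 13 that fell had a median of -0.36 and were below 0 in 11 of 13. Lists chosen alike from unchanged groups reached these counts in 50 and 73 of 100 simulations. The 95% intervals excluded a 4-fold change in either direction for 393 of the 446 probes (88.1%), and for 379 (85.0%) with slide as a block. All 3 arrays of this group lay on slide 3, with 1 control array. No probe passed with slide as a block or within that slide (limma), while Ealb_Met_P10_G3_SP6_2090800 alone passed with quantile normalization (adjusted p = 0.0279) and with brightness as a covariate (adjusted p = 0.00468), within 0.00468 to 1 over its 31 alternatives.

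Between 200 and 100 mg/kg of Ag-NP no probe passed in limma, with 31 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0967, for Ealb_Met_P8_C1_SP6_2090691 at -1.90 ± 0.39 (SE). P2_C1_T7_1328895 had 2.23 ± 0.73, Ealb_Met_P6_D6_SP6_2090551 had 1.67 ± 0.55 and Ealb_Met_P6_D3_SP6_2090528 had -1.18 ± 0.35, each with an adjusted p of 0.586. Ealb_Met_P8_C1_SP6_2090691 was above background on 2 of 3 arrays at 200 mg/kg, and Ealb_Met_P6_D6_SP6_2090551 on 2 of 3 at 100 mg/kg. No probe passed in limma with slide as a block or within slide 3, and 8 fell without Ag-NP 200 mg/kg replicate 1.

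The silver forms differed at 100 mg/kg in 5 probes, 1 higher and 4 lower with Ag-NP than with AgNO3 (limma). P5_D7_T7_1329838 was 6.42-fold higher with Ag-NP, at 3.28 ± 0.27 (SD, n = 3) against 0.60 ± 0.55, a log2 difference of 2.68 ± 0.57 (SE, adjusted p = 0.0315). Ealb_Met_P6_D6_SP6_2090551 was 5.57-fold lower, at -1.14 ± 1.25 against 1.34 ± 0.77 (adjusted p = 0.042), with 2 of the 3 Ag-NP arrays above background. P1_F2_T7_1328821 was at least 1.14-fold lower with Ag-NP, where no array measured it above background (adjusted p = 0.0118). The other 2, named after their values were seen, were Ealb_Met_P10_G3_SP6_2090800 and Ealb_Met_P10_F3_SP6_2090799, at least 1.24-fold and 1.64-fold lower with Ag-NP (adjusted p = 0.0164 and 0.0172), where no array measured either above background. A set of 30 probes was above background on all 3 AgNO3 and on none of the 3 Ag-NP arrays at 100 mg/kg, and none showed the opposite. The AgNO3 arrays at 100 mg/kg had 455 to 589 probes above background and a negative-control spread of 3.03 to 3.72, against 355 to 483 probes and a spread of 4.27 to 9.87 on the Ag-NP arrays, which lay on slide 3.

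No slide held both groups at 100 mg/kg, so the difference between forms could not be tested within a slide. Only P5_D7_T7_1329838 passed with slide as a block (adjusted p = 0.02, 0.00971 to 0.151 over its 31 alternatives). With brightness as a covariate 2 were higher and 16 lower, all 5 probes among them. The count of 5 fell to 0 without AgNO3 100 mg/kg replicate 3 or Ag-NP 100 mg/kg replicate 3, to 1 without AgNO3 100 mg/kg replicate 1, and to 3 without control replicate 2 or AgNO3 200 mg/kg replicate 2. The single higher and 4 lower probes became 1 and 12 with array median scaling, 2 and 3 with the percentile of probes above background on all arrays, 0 and 4 in the authors' values and 0 and 5 with spike-in scaling.

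At 200 mg/kg the silver forms also differed in 5 probes, 3 higher and 2 lower with Ag-NP than with AgNO3 (limma), and none of them was among the 5 at 100 mg/kg. No probe passed for the interaction of form and concentration, so this does not show that other probes respond at each concentration. Contig11 was 9.76-fold higher with Ag-NP, at 0.91 ± 0.12 (SD, n = 3) against -2.38 ± 1.42, a log2 difference of 3.29 ± 0.68 (SE, adjusted p = 0.0335), with 2 of the 3 AgNO3 arrays not well above background, so the size is uncertain. P2_5A_T7_1328919 was at least 2.04-fold higher, as no AgNO3 200 mg/kg array measured it above background (adjusted p = 0.0315). Ealb_Met_P8_C1_SP6_2090691 was 5.45-fold lower, at -1.61 ± 0.73 against 0.84 ± 0.38 (adjusted p = 0.00733), with 2 of the 3 Ag-NP arrays above background. Ealb_Met_P6_D3_SP6_2090528 was 3.16-fold lower (adjusted p = 0.0335). The fifth, Ealb_Met_P4_A3_T7_2175248, named after its value was seen, had a log2 difference of 1.71 ± 0.38 (adjusted p = 0.0394). A set of 14 probes was above background on all 3 Ag-NP and on none of the 3 AgNO3 arrays at 200 mg/kg, with none the other way. The Ag-NP arrays at 200 mg/kg had 427 to 469 probes above background and the AgNO3 arrays 251 to 477.

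Between forms at 200 mg/kg 139 probes had an unadjusted p below 0.05 in limma, beside 22.3 by chance. The groups' arrays did not overlap in 35.2% of the tested probes, beside 10% by chance. Probes that move together spread more widely around these chance values. The first principal component alone placed the AgNO3 arrays (-0.48 to -0.22) below the Ag-NP arrays (-0.03 to 0.15). The excess therefore does not show how many probes differed between forms. The 35 probes that rose with AgNO3 had a median difference of -0.84 and lay below 0 in 35 of 35, though none passed adjusted over the list alone or over all probes. The 13 that fell with AgNO3 had a median difference of 1.40, and 10 passed adjusted over the list alone and 2 over all probes. Both lists were chosen for their AgNO3 values, which enter the difference, so neither count is independent evidence.

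Only Ealb_Met_P8_C1_SP6_2090691 passed at 200 mg/kg with slide as a block (adjusted p = 0.0171, 0.00049 to 0.729 over its 32 alternatives), and within slides 1 and 3 alone 38 and 0 probes passed in limma. With brightness as a covariate 59 were higher and 18 lower, all 5 probes among them. No probe passed without Ag-NP 200 mg/kg replicate 2 or 3, and 40 did without its replicate 1. The count was 1 without control replicate 2 or AgNO3 200 mg/kg replicate 2, 3 without control replicate 1, 9 without control replicate 3 or Ag-NP 100 mg/kg replicate 2, 11 without AgNO3 100 mg/kg replicate 3, 19 without Ag-NP 100 mg/kg replicate 1 and 20 without AgNO3 200 mg/kg replicate 1. The 3 higher and 2 lower probes became 10 and 1 in the authors' values, 19 and 1 without the 3 arrays of high negative-control spread, 11 and 8 with quantile normalization, and 2 and 6 with no filter.

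**Figure D2:**
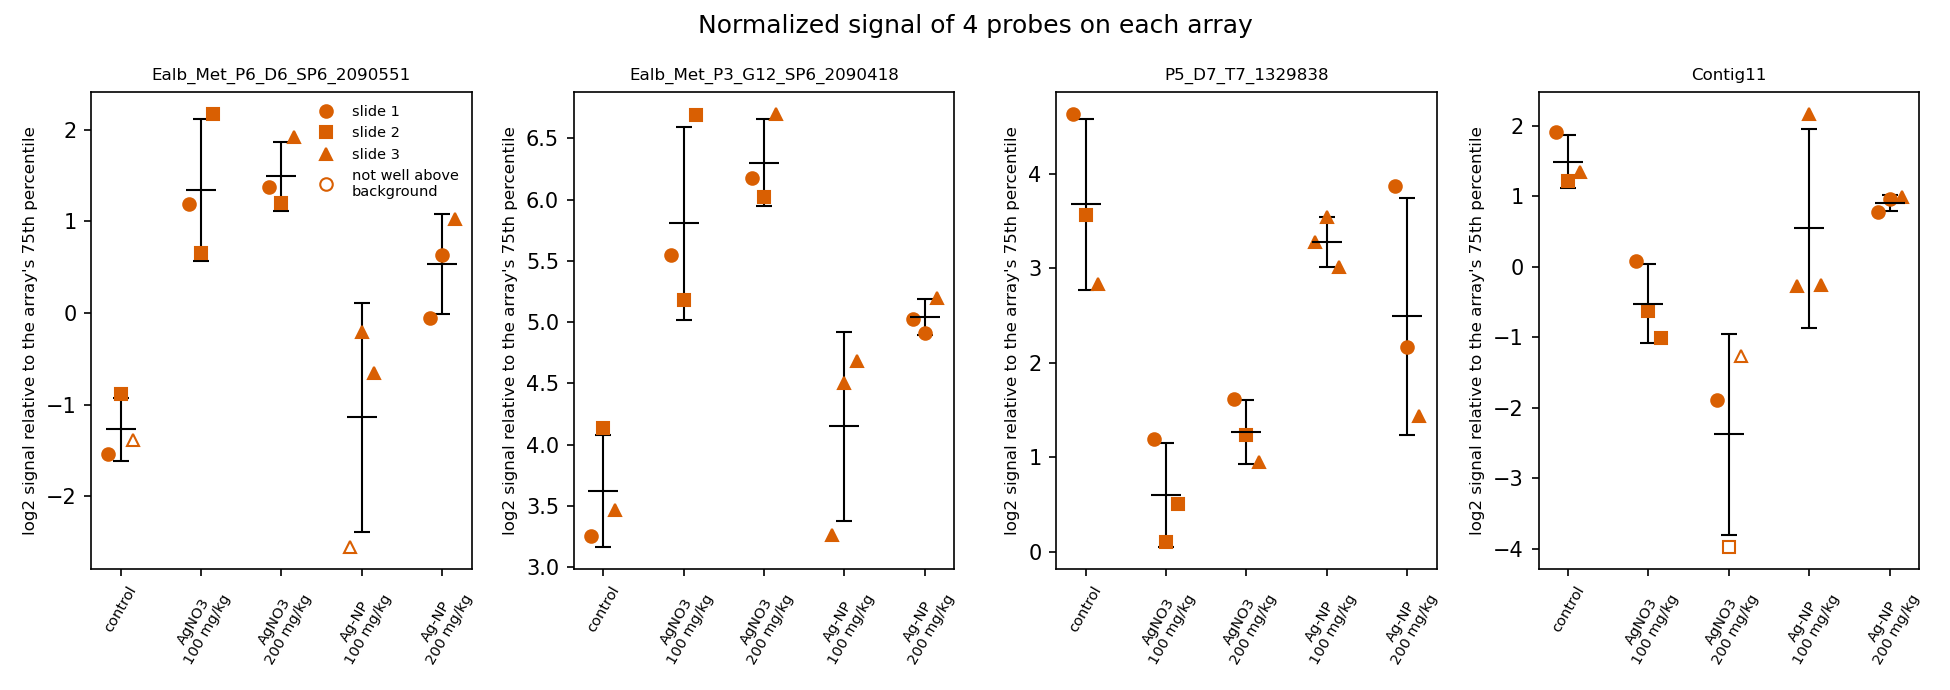
Log2 signal relative to the array's 75th percentile of 4 named probes on each of the 15 arrays, by group, with the marker's shape for the slide, open markers for arrays not well above background, and horizontal bars for the mean and SD of 3 arrays. P5_D7_T7_1329838 lay at 0.60 with AgNO3 at 100 mg/kg and at 3.28 with Ag-NP at 100 mg/kg, beside 3.68 in control.

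**Figure D3:**
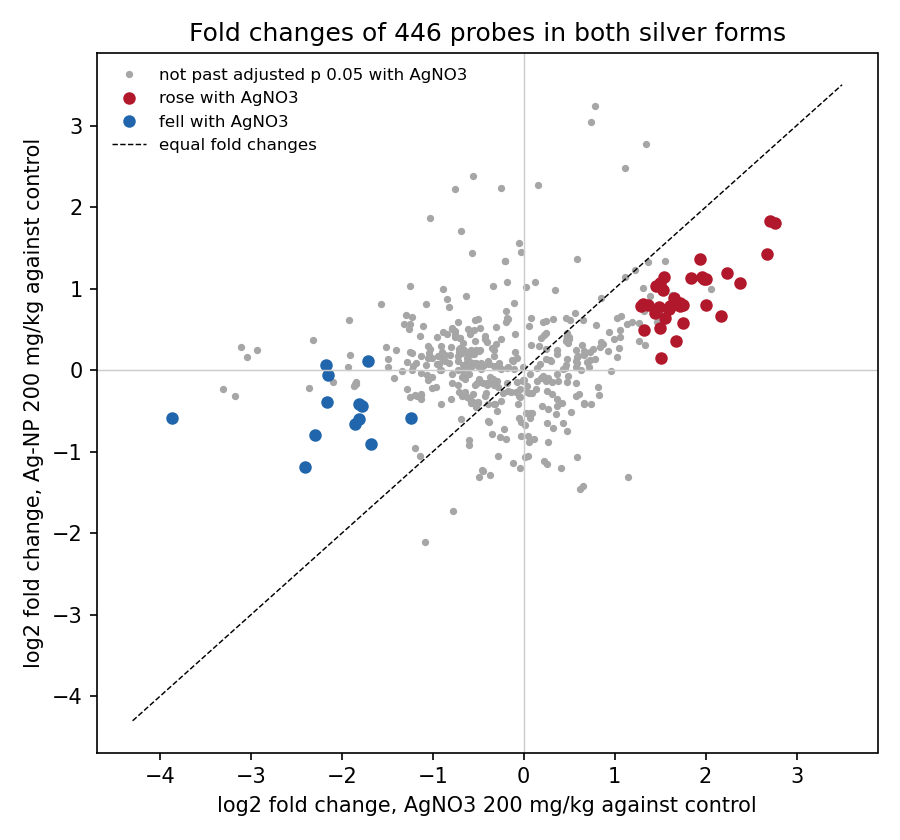
Log2 fold change against control of the 446 tested probes with AgNO3 at 200 mg/kg (horizontal axis) and Ag-NP at 200 mg/kg (vertical axis), 1 point per probe, with the 35 probes that rose with AgNO3 in red, the 13 that fell in blue and a dashed line of equal fold changes. All 35 red points lie above 0 on the vertical axis, and across all points Pearson's r was 0.34.

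Across the 446 probes the fold changes of the 2 forms correlated at Pearson's r = 0.52 and Spearman's rho = 0.51 at 100 mg/kg, where unchanged groups sharing the control arrays gave 0.40 ± 0.33 (SD of 100 simulations). The covariance was 0.160 beside a simulated 0.151 ± 0.183, a difference of 0.00969. At 200 mg/kg r was 0.34 and rho 0.29, beside a simulated 0.49 ± 0.27, and the covariance was 0.226 beside 0.156 ± 0.158, a difference of 0.0697. Fitted with slide as a block r was 0.30 at 100 mg/kg and 0.35 at 200 mg/kg. Within slides 1 and 3 alone it was 0.67 and 0.45 at 200 mg/kg, and no slide held the 3 groups needed at 100 mg/kg. These are correlations across probes, which are not independent replicates. Those without a block over all slides lie within the range that shared controls gave, and no range was simulated for the others.

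No probe passed in limma for the interaction of form and concentration, with 51 at an unadjusted p below 0.05. Ealb_Met_P8_C1_SP6_2090691, which was lower with Ag-NP than with AgNO3 at 200 mg/kg, had an interaction of -2.56 ± 0.55 (SE, adjusted p = 0.152). Ealb_Met_P3_F6_SP6_2090372 had 2.82 ± 0.69 (adjusted p = 0.159) and P3_E8_T7_1329707 had -2.28 ± 0.75 (adjusted p = 0.372). P2_B12_SP6_1371407 (adjusted p = 0.159) was not well above background on any AgNO3 200 mg/kg array, so no size is given for it. No probe passed in limma with slide as a block either. With brightness as a covariate 6 did, and 3 did without Ag-NP 200 mg/kg replicate 1.

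Over the mean of the 4 silver groups against control no probe passed in limma, and 50 had an unadjusted p below 0.05. Ealb_Met_P3_G12_SP6_2090418 had a log2 difference of 1.70 ± 0.36 (SE), P5_F3_T7_1329810 had 1.31 ± 0.30 and P5_D7_T7_1329838 had -1.77 ± 0.45, each with an adjusted p of 0.103, and P3_B4_SP6_1371433 had -1.63 ± 0.47 (adjusted p = 0.113). None passed in limma with slide as a block. The count was 10 with array median scaling, 22 without Ag-NP 100 mg/kg replicate 1 and 2 without AgNO3 100 mg/kg replicate 2.

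By kind of probe name, the tested probes comprised 91 Contig, 167 Ealb_Met, 70 Ealb_Pest and 118 other clone names. With AgNO3 at 200 mg/kg, 4 Contig probes rose and 1 fell, 14 Ealb_Met probes rose and 3 fell, 2 Ealb_Pest probes rose and 2 fell, and 15 probes of other clone names rose and 7 fell. The last kind held 22 of the 48 changed probes, and 18.6% of its 118 probes changed. Against the other kinds together, a two-sided Fisher's exact test gave p = 0.00275. This did not pass after adjustment (adjusted p = 0.055 over the 40 tests of 4 kinds in 10 comparisons). The 40 include tests in comparisons without a changed probe, which could not give a small p and raised the adjusted value. With AgNO3 at 100 mg/kg the other clone names held 8 of the 11 rises and both falls (Fisher's exact p = 0.000167, adjusted p = 0.00668), and the other 3 rises were Ealb_Met probes. The kinds were set after the names were seen. These tests treat probes as independent, although many had like profiles: at a correlation of at least 0.9 over the arrays, the 48 probes formed 19 groups, the largest with 8 probes, and the 13 formed 8. For AgNO3 at 200 mg/kg, Fisher's exact p was 0.239 with no filter on dim probes, 0.273 with spike-in scaling and 0.257 without the 3 arrays of high negative-control spread. In the authors' values the share was not above that of the other kinds. Fisher's exact p was 1.13e-05 with quantile normalization, 8.03e-05 with normexp, 0.000144 with slide as a block and 0.00644 with brightness as a covariate. Leaving out each array in turn gave 0.000366 to 0.0243. The share at 100 mg/kg was not tested under the alternatives, and its 13 calls became 0 with no filter and 2 with slide as a block. Tested as sets with camera, no kind moved against the others in any of the 10 comparisons, with a smallest adjusted p of 0.179 for Ealb_Pest with AgNO3 at 200 mg/kg (adjusted p = 0.962 with an estimated correlation, adjusted p = 0.192 with slide as a block). The planned lists of metal-binding, oxidative-stress, chaperone and other genes could not be compared, because the probe names carry no gene names.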

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

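The tests of array brightness, of slide for the difference between forms and for Ag-NP at 100 mg/kg, of whether 1 slide carried the AgNO3 effect, and of the spread of Ag-NP arrays without single arrays were chosen after the result was seen. The other tests in this part were set before.

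The response differed between the silver forms in 5 probes at 100 mg/kg and in 5 probes at 200 mg/kg, by limma's test of the difference itself with 3 arrays per group. At 100 mg/kg P5_D7_T7_1329838 fell with AgNO3 and had a log2 difference from control of -0.40 with Ag-NP (adjusted p = 0.996). At 200 mg/kg Contig11 fell with AgNO3 and had -0.59 with Ag-NP (adjusted p = 0.843).

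The 5 probes that differed between forms at 200 mg/kg kept 102% of their median difference with brightness as a covariate and all 5 passed. The groups' mean log2 brightness was close, at 4.456 with AgNO3 and 4.545 with Ag-NP, so the covariate could move these differences little. The share kept therefore decides little about brightness. With slide as a block the 5 probes kept 95.9% (2.24 to 2.15 log2 units, median standard error 0.39 to 0.43), but only 1 of 5 still passed. The placement of the groups on the slides let the block move differences little, by a median of 0.0744 log2 units over all tested probes. The 5 were also chosen for large differences, so the share kept decides little about slide. The median error grew and the median difference shrank, while single differences moved both ways (Ealb_Met_P6_D3_SP6_2090528 from -1.66 to -1.70, adjusted p = 0.115, and Contig11 from 3.29 to 2.89, adjusted p = 0.0999), and which of these ended the calls was not tested. The 10 splits of 3 arrays against 3 are too few for a share under 0.05, and the real split gave 5 probes, the highest of the others 0, with 1 split at the real count. A hypothesis for these probes is a response that depends on the silver form, and what the salt and the particles differ in, dissolved silver included, was not measured here.

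Among the 48 probes changed with AgNO3 at 200 mg/kg, with brightness as a covariate those that rose kept 88.5% of their median fold change (1.66 to 1.47, median standard error 0.43 to 0.40) and 20 of 35 passed, and those that fell kept 113% (-1.85 to -2.10) and 11 of 13 passed. Mean log2 brightness was 4.933 in control and 4.456 with AgNO3. Within the AgNO3 arrays its SD was only 0.0722, so the other groups set the slope almost alone. The 48 were also chosen for large differences, so the share kept decides little about brightness. The differences of AgNO3 and control arrays on slides 1, 2 and 3 correlated across the 446 probes at 0.609, 0.214 and 0.438, the lowest being 0.214, and the lowest of 3 reached that in 81 of 1000 simulations with unchanged arrays. An effect carried by 1 slide therefore cannot be told apart from the exposure, with 1 array of each group per slide. A direction alike on all 3 slides in 100% of the 48 probes decides nothing, because the probes were chosen for it, and 47.0% of the other tested probes showed it too, where chance gives 25%. A shift common to all arrays of a slide cancels by design, as both groups had 1 array on every slide. Of the 10 splits, 1 reached the real count of 48, and the highest of the others gave 38 by setting AgNO3 200 mg/kg replicate 1 beside control replicates 1 and 2, which places slides 1, 1 and 2 against 2, 3 and 3, while with slide as a block 24 of the 48 passed. The even placement of both groups on the slides fixes the fold changes (median size 1.53 in the 24 that no longer passed), while the median error went from 0.44 to 0.47, the block took 2 residual degrees of freedom and the adjustment changed with the other probes. Which of these ended the calls was not tested.

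Neither Ag-NP group had a probe past the threshold. For Ag-NP at 100 mg/kg, 0 probes passed with slide as a block or within slide 3, and 85.0% of the probes had an interval that excluded a 4-fold change, so a masked change in the remaining probes and slide cannot be told apart, with all 3 arrays on 1 slide. For Ag-NP at 200 mg/kg the median SD within the group was 0.841 times that with AgNO3. It stayed below 1.5 times, the size set before, without any 1 of the 6 arrays (0.346 to 1.32). The fit pools the spread of all groups, and the median standard error was 0.449 in both comparisons with control. A larger spread of the Ag-NP arrays could therefore not have given their comparison a larger error, and the ratio does not test that reason for fewer probes. The real count of 0 is reached by 10 of 10 splits whatever the data, so the splits say nothing here about chance for Ag-NP at 100 mg/kg (highest other 7) or at 200 mg/kg (highest other 0). A smaller response to Ag-NP than to AgNO3 at 200 mg/kg stays a hypothesis.

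For the remaining comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. AgNO3 at 100 mg/kg gave 13 probes beside a highest other of 0, with 1 split at the real count, and the forms at 100 mg/kg gave 5 beside 0, again 1 split. The concentrations of AgNO3 gave 0 beside 0 and those of Ag-NP gave 0 beside 19, and 10 splits reach a count of 0 whatever the data. The split that gave 19 placed Ag-NP 100 mg/kg replicate 1 with Ag-NP 200 mg/kg replicates 2 and 3, and each side of it held slides 1, 3 and 3. It set the 3 brightest of the 6 arrays (24.2, 31.1 and 44.5) against the 3 dimmest (16.9, 17.3 and 18.6), so this split ran along brightness. Whether brightness gave its 19 calls was not tested. Likewise all 100 drawn regroupings reach a real count of 0, for the interaction (highest other 55) as for all silver against control (highest other 32), which decides nothing about chance. A regrouping can bring arrays of a real group together, as the one with 32 did by setting AgNO3 200 mg/kg replicates 1 and 2 with control replicate 3 against the rest. The one with 55 set arrays of log2 brightness 4.08 to 4.53, all AgNO3 200 mg/kg arrays among them, against arrays of 4.30 to 5.76. It thus ran partly along brightness, and what gave the 55 and 32 calls was not tested.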

How the results depend on the processing

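The alternatives with brightness, spike-in scaling, arrays of high negative-control spread left out, slide with brightness, and single slides were chosen after the data were seen. The other alternatives were planned. Except where a construction is named, the cause of a change was not tested.

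Under the planned scalings and sources, quantile normalization gave 22 probes for AgNO3 at 100 mg/kg (13 without it), 1 for Ag-NP at 100 mg/kg (0), and 11 and 19 for the forms at 100 and 200 mg/kg (5 and 5). Normexp gave 0 and 19 for the forms, and the array median gave 13 and 2 for the forms and 10 for all silver (0). The percentile of probes above background on all arrays gave 2 for AgNO3 at 100 mg/kg. The authors' values gave 0 and 8 for AgNO3 at 100 and 200 mg/kg (13 and 48), 11 for the forms at 200 mg/kg and 4 between AgNO3 concentrations (0). No filter, which tests 1035 probes, gave 0, 13, 0 and 8 for AgNO3 at 100 and 200 mg/kg and the forms at 100 and 200 mg/kg. Only probes above background on all arrays gave 0 and 0 for the forms, and eBayes with trend and robust gave 11 for the forms at 200 mg/kg. A fit of only the arrays compared, with fewer arrays to estimate the spread, gave 0 for AgNO3 at 100 mg/kg, 0 and 21 for the forms and 16 between AgNO3 concentrations. A 2-fold minimum moved no count and could not, because the smallest change among changed probes (1.24 log2 units) already exceeded it.

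The replicate numbers partly follow the slides. In control and with AgNO3 at 200 mg/kg, replicates 1, 2 and 3 lay on slides 1, 2 and 3, so the replicate block is not a check separate from slide. The pairing was checked on deviations from the group means. Same-numbered arrays correlated above 0.1 in 10 of 30 pairs (-0.505 to 0.742), in no pair of groups for all 3 numbers, and 7 of 15 arrays correlated best with their own number, so the numbers do not pair the arrays. The replicate block gave 8 and 48 for AgNO3 at 100 and 200 mg/kg, 8 and 1 for the forms at 100 and 200 mg/kg, 2 for all silver and 0 elsewhere in limma.

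The slide block gave 2 and 24 for AgNO3 at 100 and 200 mg/kg and 1 and 1 for the forms. Slide with brightness gave 6 and 21 for AgNO3, 3 and 28 for the forms and 13 between AgNO3 concentrations. Within slide 1, with 1 residual degree of freedom, 2 probes passed for AgNO3 at 100 mg/kg, 15 for Ag-NP at 200 mg/kg, 38 for the forms at 200 mg/kg and 29 between AgNO3 concentrations, and the correlation between forms at 200 mg/kg was 0.665 (0.335 over all slides). Within slide 2, 0 passed for AgNO3 at 100 mg/kg and 1 at 200 mg/kg, and within slide 3, 0 for AgNO3 at 200 mg/kg and 0 for the forms at 200 mg/kg. Brightness gave 21 for AgNO3 at 100 mg/kg, 1 for Ag-NP at 100 mg/kg, 18 and 77 for the forms and 6 for the interaction. Spike-in scaling gave 3 and 18 for AgNO3 and 0 for the forms at 200 mg/kg. Without the 3 arrays of high negative-control spread, 6 passed for AgNO3 at 100 mg/kg, 55 for AgNO3 at 200 mg/kg (20 rises and 35 falls, against 35 and 13, with 28 of the 55 among the 48), 1 and 20 for the forms, 3 between Ag-NP concentrations and 12 for the interaction.

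Leaving out each of the 15 arrays gave 0 to 25 probes for AgNO3 at 100 mg/kg, 8 to 59 at 200 mg/kg, 0 for Ag-NP at 100 mg/kg in all 15 fits and 0 to 9 at 200 mg/kg. The range was 0 to 7 and 0 to 40 for the forms at 100 and 200 mg/kg, 0 to 26 and 0 to 8 between concentrations of AgNO3 and Ag-NP, 0 to 3 for the interaction and 0 to 22 for all silver. The correlations between forms ranged from 0.346 to 0.647 at 100 mg/kg and 0.199 to 0.533 at 200 mg/kg.

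Other clone names held 22 of the 48 probes changed with AgNO3 at 200 mg/kg. This share had an adjusted p of 0.055 (Fisher's exact test) over 40 tests, some of which could not give a small p. Their share was not above that of the other kinds in the authors' values (2 of 8), where so few probes show no reversal. Nor was it within slides 1 and 2, where 1 array against 1 shows no reversal either. Of 322 counts of name kinds that moved under the alternatives, 316 were 0. Of 1232 values of named probes under alternatives, 1047 kept their direction and side of the threshold, 156 lost a call, 29 gained one and 0 reversed. The 1232 include named probes that had not passed and so had no call to lose. Among the named calls, losses ranged from 1 of 33 alternatives for Contig11 with AgNO3 at 200 mg/kg to 17 of 30 for Ealb_Met_P6_D6_SP6_2090551 between forms at 100 mg/kg. Low signal left 589 of 1035 probes untested, and the array with the fewest had 251 probes above background.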

Other observations

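The test of the read end in this part was chosen after the result was seen.

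Clone names in the files carry T7 or SP6 before a final number, the promoters at both ends of common cloning vectors, here taken to name the end a clone was read from. Among Ealb_Pest probes 18 of 24 T7 names (75%) were bright enough to be tested, against 52 of 174 SP6 names (29.9%, two-sided Fisher's exact p = 4.12e-05). Among Ealb_Met probes these were 25 of 42 (59.5%) and 142 of 303 (46.9%, Fisher's exact p = 0.14), and among other clone names 82 of 226 (36.3%) and 36 of 95 (37.9%). A read end that sets detection in general is argued against by the last kind, with a Fisher's exact p of 0.801, so what separates the Ealb_Pest names stays open.

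Contig probes were tested most often, 91 of 171 (53.2%), followed by 167 of 345 Ealb_Met probes (48.4%), 118 of 321 other clone names (36.8%) and 70 of 198 Ealb_Pest probes (35.4%). The spread of the negative-control spots ranged from 2.49 to 12.6 over the arrays, and all 3 arrays above 7 were on slide 3: control replicate 3, AgNO3 200 mg/kg replicate 3 and Ag-NP 100 mg/kg replicate 1.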
